A study of Homo sapiens with 6 samples.

How the data were processed

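The study measured messenger RNA in cultures of HMLER cells, a breast cancer model made by giving human mammary epithelial cells telomerase, the SV40 early region and an activated HRAS. Per the labels' protocols, cells received either paclitaxel at 10 nM or salinomycin at 1 µM for 1 week and were then cultured without compound for 3 weeks. Total RNA was extracted, labelled with biotin and hybridised to Affymetrix expression arrays. There were 3 arrays per treatment, which the series' design text describes as biologic replicates, and no untreated arm. All differences are therefore given as salinomycin minus paclitaxel and show no change from untreated cells.

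The deposited values are 1 summarised intensity per probe set and array, and RMA is named in the submitters' processing notes. RMA corrects background, normalizes quantiles between arrays and summarises the probes of a probe set; its version, and the settings used, are not given in the sources used here. The deposited intensity values were on a linear scale, reaching 40719 at the highest. They were converted to log2 with a floor of 1, which no value reached. The medians on the log2 scale lay between 5.91 and 5.95, so no further normalization was applied. RMA compresses differences of dim probe sets, and no detection calls were used. Control probe sets for a bacterial tryptophan gene, which has no human counterpart, averaged 4.22 to 4.32 on the 6 arrays, and values of that size were treated as background. A fold measured against such a value understates the true one. The number of arrays limits the precision.

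The value table held 22277 probe sets, of which 62 controls were left out. Gene names came from the array's annotation: 19724 probe sets had 1 symbol, 568 had several and 1923 were unnamed here. Symbols were looked up by gene identifier for 19707 probe sets, and 0 needed updating. Probe sets with several symbols were named for none of them. Each gene was represented by the probe set with the highest mean over all 6 arrays, which left 12165 genes. No genome build is named for the arrays in the sources used here, so no coordinates are given.

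Differences between treatments were tested per gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 12165 genes and a threshold of 0.05 on the adjusted p. A second count required a difference of at least 2-fold. The replicate number was not used as a block. Simulated arrays with 200 changed genes were run through the same steps. With the spread of 3 against 3 arrays, 66% of genes changed 2-fold and 88% of genes changed 4-fold were recovered, with 6 false calls. With 2 against 3 arrays the shares were 95% and 100%, with 18 false calls. The simulated changes fell on randomly chosen genes with independent noise. The shares therefore do not give the recovery of genes whose spread comes from the array labelled paclitaxel replicate 3.

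Before the data were examined, 37 gene lists were fixed, covering epithelial, mesenchymal, stem-cell, cell-cycle, stress, immune, metabolic and drug-related genes and markers of other cell types. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An inter-gene correlation estimated per list, and limma's fry, were alternatives. An epithelial minus mesenchymal score was the mean log2 value of the first list minus that of the second on each array, compared with an exact permutation test. The 3-prime to 5-prime and 3-prime to middle signal of the GAPDH and ACTB control probe sets served as a sign of RNA quality and was compared in the same way.

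The genes to be named were set by a rule fixed at the same time. It takes the 12 genes with the largest increase and the 12 with the largest decrease among genes past the threshold whose groups do not overlap. It adds up to 4 members past the threshold from each list, or up to 2 of the highest level where none passed. It always adds CD44, CDH1, VIM, EPCAM, ITGA6, ITGB1, ALDH1A1, ZEB1, SNAI2, FN1, ABCB1, ABCG2, HRAS and TERT; CD24, also in the rule, is not analysed here, and 1 more gene of the rule and 1 of the 37 lists are not reported here. Symbols of the open reading frame kind are skipped. Because 0 genes passed with all 6 arrays, the same rule was also applied without the array labelled paclitaxel replicate 3, and that application was chosen after the values were seen. For lists that are only summarised, members are left out.

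Leaving out each array in turn was among the alternatives set in advance. The others were quantile normalization, median centring, an offset of 16 before log2, leaving out genes below the median level, the mean of all probe sets of a gene, leaving out probe sets of the _x_at and _s_at kinds, the replicate number as a block, a variance trend with robust eBayes, array weights, testing every probe set and a threshold of 0.01. All of them were repeated on the 5 arrays that remain without the array labelled paclitaxel replicate 3, a repeat chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.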

Results

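The data are 6 expression arrays of HMLER cells, 3 labelled paclitaxel and 3 labelled salinomycin. Paclitaxel is a taxane that stabilises microtubules, and salinomycin is an ionophore that carries potassium across membranes. Cells were exposed for 1 week and grown without compound for 3 weeks, so the arrays describe the populations that remained after treatment. The comparison asks how the populations left by the compounds differ in gene expression, in particular in genes tied to epithelial and mesenchymal states and to stem-like cells. Array medians were 5.91 to 5.95 on the log2 scale of RMA intensity. Quantile normalization within RMA brings medians together, so they do not show how bright the arrays were before it.

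The arrays fell into a pair and a set of 4 that did not follow the labels. Paclitaxel replicates 1 and 2 had a mesenchymal pattern of expression, with CDH1 (E-cadherin, the adhesion protein of epithelial junctions) at 4.18 and 4.23 and COL3A1 (a fibrillar collagen) at 13.96 and 14.23 on the log2 scale. The 3 salinomycin arrays had the opposite pattern, with CDH1 at 12.42 ± 0.10 and COL3A1 at 5.55 ± 0.54 (SD, n = 3). The array labelled paclitaxel replicate 3 had CDH1 at 12.44 and COL3A1 at 4.97, within or just below the range of the salinomycin arrays. Across all 12165 genes, which are not independent replicates, its Pearson correlations with the salinomycin arrays were 0.998, 0.998 and 0.997, and those with paclitaxel replicates 1 and 2 were 0.916 and 0.913. Paclitaxel replicates 1 and 2 correlated at 0.993, and pairs of salinomycin arrays at 0.996 to 0.998. The array labelled paclitaxel replicate 3 differed at least 2-fold from salinomycin replicates 1, 2 and 3 in 1, 1 and 46 genes and from paclitaxel replicates 1 and 2 in 1861 and 1939 genes; salinomycin replicate 3 differed so from salinomycin replicates 1 and 2 in 44 genes each.

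With all 6 arrays grouped as labelled, 0 of 12165 genes passed the threshold in limma, and the smallest Benjamini-Hochberg adjusted p was 0.355. At an unadjusted p under 0.05 there were 825 genes, where chance gives 608.25. The groups did not overlap in 1583 genes, or 13.0%, where chance gives 10%. CDH1 averaged 6.95 ± 4.76 in the paclitaxel group and 12.42 ± 0.10 in the salinomycin group (SD, n = 3 each), a log2 difference of 5.48 ± 2.35 (SE) with an adjusted p of 0.355. COL3A1 averaged 11.05 ± 5.27 and 5.55 ± 0.54, a difference of -5.50 ± 2.61. The median SD per gene was 0.185 among the paclitaxel arrays and 0.0922 among the salinomycin arrays. Leaving out the array labelled paclitaxel replicate 3 gave 4622 genes, and limma's array weights, which gave that array a weight of 0.125 and the others 0.999 to 2.63, called 4352 genes with all 6 arrays kept.

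The epithelial minus mesenchymal score was -4.12 and -4.31 in paclitaxel replicates 1 and 2 and 2.93 in the array labelled paclitaxel replicate 3. It was 2.87, 2.80 and 2.13 in the salinomycin arrays. As labelled, the groups averaged -1.84 ± 4.13 and 2.60 ± 0.41 (SD, n = 3 each), a difference of 4.44 with an exact permutation p of 0.4, two-sided, where 0.1 is the smallest p the design allows. Without the array labelled paclitaxel replicate 3 the difference was 6.82, and the exact p of 0.1 was again the smallest that can be reached.

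**Figure D1:**
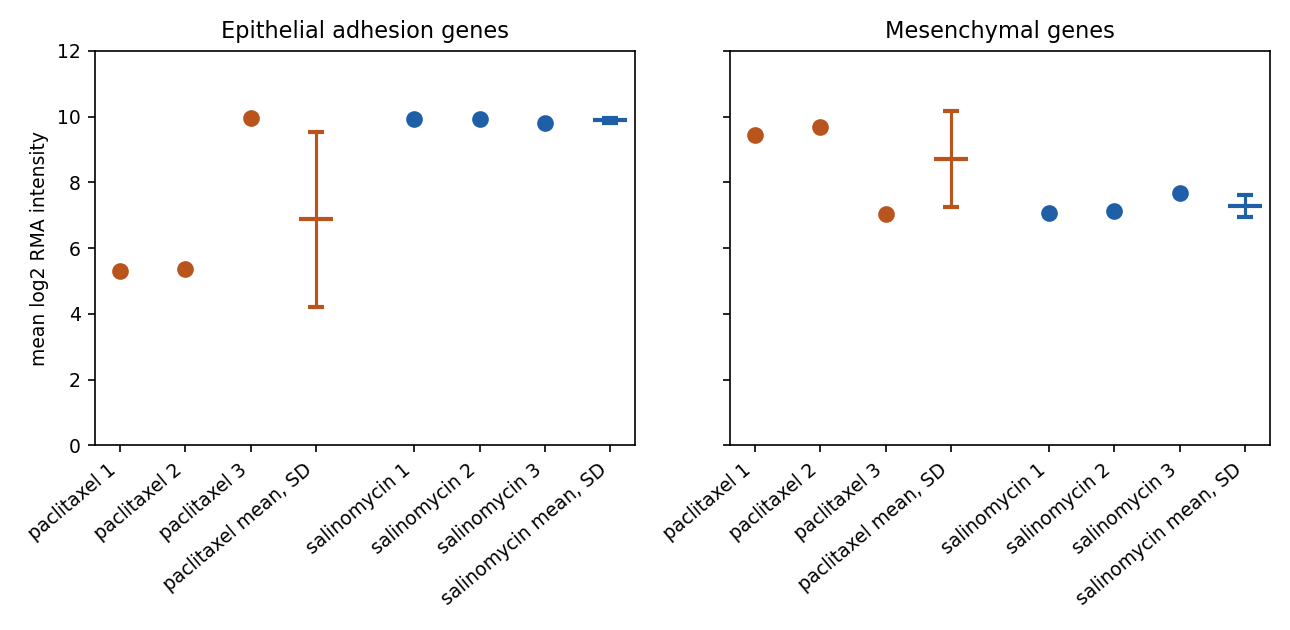
Mean log2 RMA intensity of 25 epithelial adhesion genes (left) and 34 mesenchymal genes (right) on each array, with the mean and SD of each labelled group of 3. The epithelial mean was 5.31 and 5.36 in paclitaxel replicates 1 and 2 and between 9.81 and 9.96 on the other arrays, and the mesenchymal mean was 9.44 and 9.67 against 7.03 to 7.68.

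Without the array labelled paclitaxel replicate 3, cornified-envelope, protease and cell-adhesion genes were up to 813-fold higher in the salinomycin arrays than in paclitaxel replicates 1 and 2 (SPRR1B), and collagens and other matrix genes were up to 374-fold lower (COL3A1). Of 12165 genes, 4622 passed the threshold in limma, 2155 higher and 2467 lower in salinomycin, and 1782 of them differed at least 2-fold, 870 higher and 912 lower. At least 32-fold differences numbered 86, with 70 higher and 16 lower. The groups did not overlap in 58.8% of genes. A split of 2 against 3 made without regard to the values gives 20%. The array labelled paclitaxel replicate 3 was left out after its values were seen, so 20% is not the chance level here. These p-values rest on 2 paclitaxel cultures and leave out the spread that the third paclitaxel array shows, and every gene named from here on had an adjusted p of 0.355 or more with all 6 arrays. Log2 differences below are salinomycin minus paclitaxel without that array, with the SE from limma (n = 3 and 2), and adjusted p under the threshold unless given.

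The 12 largest increases were led by SPRR1B (9.67 ± 0.10, adjusted p = 2.09e-07), a small proline-rich protein of the cornified envelope, and included SPRR1A (9.02 ± 0.09) and SPRR2B (8.18 ± 0.29) of the same family. KLK7 (9.16 ± 0.09) and KLK10 (8.81 ± 0.08) encode kallikrein proteases of squamous epithelia, and CTSV (8.09 ± 0.16) a cathepsin. LCN2 (8.79 ± 0.12) and SLPI (7.68 ± 0.11) encode secreted antimicrobial proteins. CDH1 was 299-fold higher (8.22 ± 0.09, adjusted p = 2.17e-07), a fold that its paclitaxel values limit, since at 4.18 and 4.23 they lie just below the mean signal of the bacterial controls on those arrays, 4.26 and 4.30. S100A7 (256-fold) and S100A14 (213-fold), calcium-binding proteins of squamous epithelia, and FXYD3 (220-fold), a regulator of the sodium pump, completed the set. Dim paclitaxel values may limit other folds of this set as well. In paclitaxel replicates 1 and 2 SPRR1B was at 4.86 and 4.67 and S100A7 at 4.89 and 4.56. The 12 largest decreases were led by COL3A1 (-8.55 ± 0.30, adjusted p = 1.24e-05). Of its 4 probe sets 3 passed as lower; the remaining probe set, used when those of the _x_at and _s_at kinds were left out, gave -0.0098. COL6A3 (-7.19 ± 0.34), COL1A2 (-6.71 ± 0.36) and COL6A1 (-5.10 ± 0.47) encode further collagen chains, and PCOLCE (-5.59 ± 0.11) an enhancer of procollagen processing. FBLN5 (-7.41 ± 0.69), MGP (-6.77 ± 0.22), SPARCL1 (-6.68 ± 0.20) and DPT (-5.55 ± 0.22) encode other matrix proteins, ENPP2 (-5.40 ± 0.21) a secreted lysophospholipase, and CDH11 (-5.59 ± 0.32) a cadherin of mesenchymal cells. CADM3 was at -6.07 ± 0.39, but at 0.081 once probe sets of those kinds, which can match several transcripts, were left out.

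**Figure D2:**
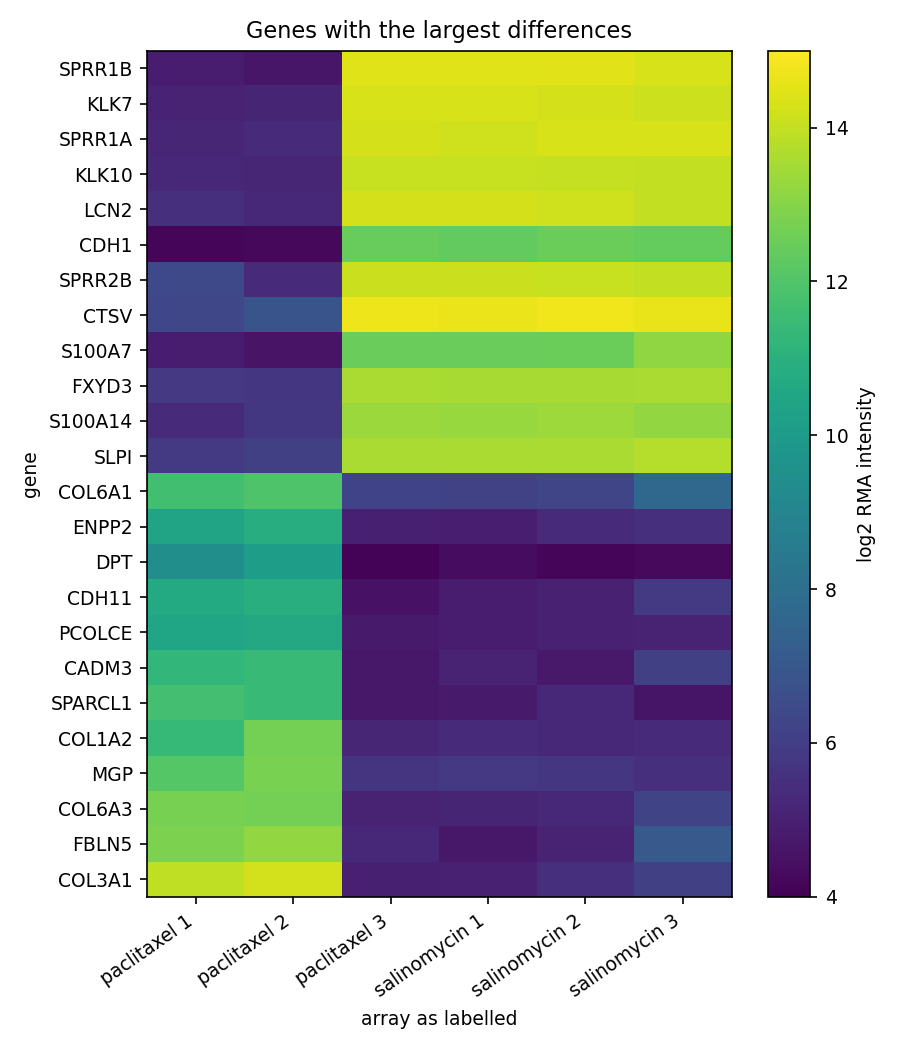
Log2 RMA intensity (colour scale, 4 to 15) of the 12 genes with the largest increase and the 12 with the largest decrease, in rows, on each of the 6 arrays as labelled, in columns. The array labelled paclitaxel replicate 3 shows the colours of the salinomycin arrays in all 24 rows, with SPRR1B at 14.44 and COL3A1 at 4.97.

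Epithelial adhesion genes were higher in the salinomycin arrays as a group. Of 25 measured members 24 were higher, 0 were lower and 1 did not pass, with 24 higher and 0 lower when adjusted over the list alone, and the median difference was 4.74. EPCAM (7.55 ± 0.12), an epithelial surface protein, ESRP1 (7.34 ± 0.10), a splicing regulator of epithelial isoforms, and RAB25 (7.21 ± 0.07), a trafficking GTPase, followed CDH1. The list passed camera at an adjusted p of 1.89e-21, and had an adjusted p of 0.264 with an estimated correlation.

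Mesenchymal genes were lower in the salinomycin arrays. Of 34 measured members 26 were lower, 1 was higher and 7 did not pass, or 29 lower and 1 higher when adjusted over the list alone, with a median of -2.19. VIM, the intermediate filament of mesenchymal cells, was at -3.24 ± 0.46. Among transcription factors of the mesenchymal state, ZEB1 was at -4.76 ± 0.18, PRRX1 at -4.30 ± 0.08 and SNAI2 at -2.11 ± 0.18. FN1 (fibronectin) was at -0.98 ± 0.14 and FBN1 (fibrillin) at -4.87 ± 0.64. The list's camera adjusted p was 2.03e-10, and 0.321 with an estimated correlation. Matrix genes followed the same course, with 29 of 35 members lower, 1 higher and 5 not past the threshold, also when adjusted over the list alone, and a median of -2.64. Their camera adjusted p was 2.39e-12, and 0.321 with an estimated correlation. Salinomycin replicate 3 lay between the groups in part of these genes: VIM was 12.43 there against 10.77 and 11.20 in salinomycin replicates 1 and 2, and the mesenchymal mean was 7.68 against 7.05 and 7.12. Fibroblast and stroma markers, of which 11 of 15 are also in other lists, moved with these groups: 9 of 15 were lower, 1 was higher and 5 did not pass, or 12 lower and 1 higher when adjusted over the list alone. Their camera adjusted p was 0.000131, and 0.352 with an estimated correlation.

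Genes of squamous and other epithelial lineages were higher in salinomycin. In the cornified envelope list 35 of 40 members were higher, 0 were lower and 5 did not pass, also when adjusted over the list alone, with a median of 4.07, a camera adjusted p of 1.89e-21 and an adjusted p of 0.0511 with an estimated correlation. In the desmosome and keratinocyte junction list 13 of 16 were higher, 1 was lower and 2 did not pass (13 and 2 adjusted over the list alone), among them the desmosomal cadherins DSC2 (6.47 ± 0.13) and DSG3 (4.82 ± 0.23) and JUP (plakoglobin, 4.32 ± 0.22). Its camera adjusted p was 2.67e-07, and 0.264 with an estimated correlation. Basal and myoepithelial genes included 17 of 23 higher, 3 lower and 3 not past the threshold, also when adjusted over the list alone, among them the keratins KRT15 (7.29 ± 0.31) and KRT16 (6.54 ± 0.09) and the cadherin CDH3 (5.19 ± 0.11). Their camera adjusted p was 2.67e-07, and 0.309 with an estimated correlation. Of luminal genes 12 of 26 were higher, 1 was lower and 13 did not pass (13 higher and 2 lower adjusted over the list alone), with a camera adjusted p of 2.61e-05, and 0.321 with an estimated correlation. The members that differed most were LCN2, SLPI, WFDC2 (5.27 ± 0.19), a secreted protein of the same inhibitor family as SLPI, and ELF3 (5.21 ± 0.10), an epithelial transcription factor.

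Genes tied to stem and progenitor cells went both ways. Of 31 measured members 5 were higher, 6 were lower and 20 did not pass, also when adjusted over the list alone, and the list had a camera adjusted p of 0.590. ALDH1A3, an aldehyde dehydrogenase, was at 6.18 ± 0.27, SOX9, a progenitor transcription factor, at 3.24 ± 0.23 and ITGA6, an integrin of basal cells, at 1.70 ± 0.13. NES (nestin) was at -2.50 ± 0.19 and PROCR, a surface receptor, at -1.93 ± 0.17. CD44, a surface marker used to sort stem-like breast cancer cells, was at -0.33 ± 0.08 (adjusted p = 0.0213). Of its 8 probe sets 1 passed as lower and 2 as higher, and their mean gave 0.17. Among fits with at least 2 arrays per group, the call was lost without salinomycin replicate 1 or 2. It was also lost with the replicate number as a block and with the mean of probe sets. The adjusted p of CD44 ran from 0.00482 to 0.185 over 14 alternatives. Without paclitaxel replicate 2, a fit that leaves 1 paclitaxel array and is not read for its call here, its difference was -0.28. ITGB1 was at -0.24 ± 0.08 (adjusted p = 0.0697), and its adjusted p ran from 0.0175 to 0.651 over 14 alternatives, passing with quantile normalization, with the offset before log2, with an intensity trend and robust eBayes and without paclitaxel replicate 1. ALDH1A1 was near background on all arrays, at -0.14 ± 0.08 (adjusted p = 0.259).

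Genes of mitosis and of DNA replication were lower in salinomycin. For mitosis, 25 of 41 members were lower, 0 were higher and 16 did not pass, or 33 lower and 0 higher when adjusted over the list alone, with a median of -1.31, a camera adjusted p of 1.19e-07 and an adjusted p of 0.609 with an estimated correlation. TOP2A, a topoisomerase of dividing cells, was at -3.11 ± 0.45, BIRC5 (survivin) at -3.02 ± 0.70, KIF20A, a mitotic kinesin, at -2.66 ± 0.74 and CDC20, an activator of the anaphase-promoting complex, at -2.59 ± 0.51. The paclitaxel cultures themselves differed here, with KIF20A at 6.15 and 8.92 and a list mean of 6.96 and 8.25 in replicates 1 and 2, against 6.06 to 6.13 in the other arrays. The list's median was -2.09 without paclitaxel replicate 1 and -0.715 without paclitaxel replicate 2. The count of lower members was 39 without paclitaxel replicate 1, 12 without salinomycin replicate 1, 11 without salinomycin replicate 2 and 15 without salinomycin replicate 3. KIF20A and BIRC5 missed the threshold when any salinomycin array was left out, and CDC20 missed it without salinomycin replicate 2. BIRC5 also missed it without probe sets of the _x_at and _s_at kinds, and KIF20A with the offset before log2 and with an intensity trend and robust eBayes. For DNA replication, 23 of 44 members were lower, 1 was higher and 20 did not pass (28 and 1 adjusted over the list alone), with a camera adjusted p of 4.42e-06, and 0.321 with an estimated correlation. RRM2, a ribonucleotide reductase subunit, was at -2.96 ± 0.47, TYMS (thymidylate synthase) at -2.17 ± 0.16, and the origin-licensing and initiation factors MCM10 and CDC6 at -2.11 ± 0.11 and -1.93 ± 0.24.

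Interferon-response and inflammatory genes were higher in salinomycin. Of 41 interferon-response genes 24 were higher, 8 were lower and 9 did not pass (25 and 8 adjusted over the list alone), with a camera adjusted p of 1.59e-05, and 0.321 with an estimated correlation. The lower members numbered 5 without paclitaxel replicate 1 or salinomycin replicate 2. IFI27 was at 5.31 ± 0.13, HERC6 at 3.48 ± 0.07, the chemokine CXCL10 at 3.47 ± 0.24 and SAMD9 at 3.43 ± 0.12. Of 40 NF-kappaB and cytokine genes 20 were higher, 3 were lower and 17 did not pass (21 and 3 adjusted over the list alone), with a camera adjusted p of 0.000114, and 0.321 with an estimated correlation; the lower members numbered 0 without paclitaxel replicate 1 or salinomycin replicate 1 or 2. IL1RN (6.47 ± 0.14), IL18 (5.91 ± 0.12) and IL1A (5.02 ± 0.11) belong to the interleukin-1 family, which squamous epithelia also express, and MMP10 (5.15 ± 0.11) is a matrix metalloproteinase. Without probe sets of the _x_at and _s_at kinds, IL1RN was at 0.33 and IL1A at 0.16, and neither passed. The mean of the NF-kappaB and cytokine list was 7.67 in salinomycin replicate 3 against 7.36 and 7.39 in salinomycin replicates 1 and 2. In paclitaxel replicates 1 and 2 it was 6.64 and 6.13. Of 33 apoptosis regulators 14 were higher, 7 were lower and 12 did not pass (15 and 8 adjusted over the list alone), with a camera adjusted p of 0.0385, and 0.321 with an estimated correlation. They included the death ligand TNFSF10 (3.50 ± 0.08) and the proapoptotic BIK (2.80 ± 0.12). The lower members numbered 3, 3 and 4 without salinomycin replicates 1, 2 and 3, and the list's adjusted p ran from 0.0272 to 0.111 over 12 alternatives, at 0.0891 without paclitaxel replicate 2.

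Lists of genes related to the compounds' known targets and to drug handling did not pass camera. Of 36 tubulins and microtubule regulators 10 were higher, 8 were lower and 18 did not pass (12 and 8 adjusted over the list alone), with a camera adjusted p of 0.405. Microtubule-associated MAP2 was at 2.23 ± 0.26 and MAP1B at -3.55 ± 0.33. Higher members were 6 without salinomycin replicate 1 and 6 without salinomycin replicate 2. Of 31 drug efflux and metabolism genes 5 were higher, 12 were lower and 14 did not pass (6 and 13 adjusted over the list alone), with a camera adjusted p of 0.108, and of 0.0409 to 0.955 over 12 alternatives, passing without paclitaxel replicate 1. The transporter ABCC4 was at -2.28 ± 0.15, the glutathione transferase GSTA4 at -2.21 ± 0.08 and CYP1A1 at 2.21 ± 0.11. ABCB1, the efflux pump that carries paclitaxel, was close to background in salinomycin and also low in paclitaxel replicates 1 and 2, at 4.57 and 5.26. Its difference was -0.82 ± 0.20 (adjusted p = 0.0219). ABCB1 missed the threshold when any salinomycin array was left out, at 0.0747, 0.0921 and 0.0692, within a range of 0.00273 to 0.0921 over 13 alternatives. ABCG2 was at 0.22 ± 0.09 (adjusted p = 0.113). Of 31 potassium and ion transport genes, the class of transport that salinomycin alters, 9 were higher, 4 were lower and 18 did not pass (10 and 4 adjusted over the list alone), with a camera adjusted p of 0.101. By fry, an alternative that does not compare a list with other genes, the microtubule, drug and ion transport lists passed at adjusted p of 0.0184, 0.00180 and 0.000165.

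Of the genes the cells were transformed with, HRAS was at 0.39 ± 0.10 (adjusted p = 0.0263), past the threshold, but at an adjusted p of 0.108 without paclitaxel replicate 1 and of 0.0929 and 0.0821 without salinomycin replicates 1 and 3, within a range of 0.0184 to 0.126 over 14 alternatives. TERT was close to background, at 0.22 ± 0.14 (adjusted p = 0.279). HRAS and TERT had 1 probe set each, and whether these read the introduced copies was not tested. Of 31 RAS and ERK feedback targets 6 were higher, 16 were lower and 9 did not pass (6 and 17 adjusted over the list alone), with a camera adjusted p of 0.0577. The early response factor EGR1 was at -2.86 ± 0.19 and the feedback inhibitor SPRY4 at -2.81 ± 0.23, while the EGF-receptor ligands TGFA and HBEGF were at 5.41 ± 0.11 and 4.88 ± 0.15. The list passed camera at an adjusted p of 0.0386 with median centring, 0.0339 with the replicate number as a block and 0.0359 without salinomycin replicate 3. Its adjusted p ran up to 0.560 over 12 alternatives. The list's median was -0.66, and -0.76 without paclitaxel replicate 1.

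Among stress and mitochondrial lists, 3 more passed camera. Of 18 heat shock genes 10 were higher, 1 was lower and 7 did not pass, also when adjusted over the list alone, with HSPB8, a small chaperone, at 2.79 ± 0.11 and DNAJB1, a co-chaperone, at 1.20 ± 0.16; the adjusted p was 0.0168, and 0.321 with an estimated correlation. The higher members numbered 6 without paclitaxel replicate 2 and 6 without salinomycin replicate 1 or 2, and the adjusted p was 0.574 without probe sets of the _x_at and _s_at kinds, the highest of 12 alternatives, which began at 0.00761. Of 31 oxidative stress genes and NRF2 targets, taken as 1 list, 5 were higher, 14 were lower and 12 did not pass (5 and 15 adjusted over the list alone). The list had a camera adjusted p of 0.0297, and 0.321 with an estimated correlation. NQO1 (-1.92 ± 0.13), AKR1C1 (-1.66 ± 0.24) and EPHX1 (-1.57 ± 0.08) encode detoxifying enzymes. This list's adjusted p was 0.528 without the same kinds of probe sets, the highest of its 12 alternatives, which began at 0.0227. Of 44 oxidative phosphorylation genes 2 were higher, 14 were lower and 28 did not pass, also when adjusted over the list alone, with NDUFV1 at -0.88 ± 0.11 and SDHA at -0.67 ± 0.08; the adjusted p was 0.0168, and 0.321 with an estimated correlation. The lower members numbered 8 without salinomycin replicate 1, the higher members 0 without paclitaxel replicate 1 or salinomycin replicate 1 or 2, and the adjusted p ran from 0.00573 to 0.0715 over 12 alternatives, the highest without genes below the median level. The unfolded protein response list did not pass (adjusted p = 0.101), with 5 of 29 higher, 12 lower and 12 not past the threshold (7 and 14 adjusted over the list alone), and the lower count was 5, 6 and 6 without salinomycin replicates 1, 2 and 3. It passed at an adjusted p of 0.00563 without paclitaxel replicate 1, the lowest of 12 alternatives, which reached 0.186.

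**Figure D3:**
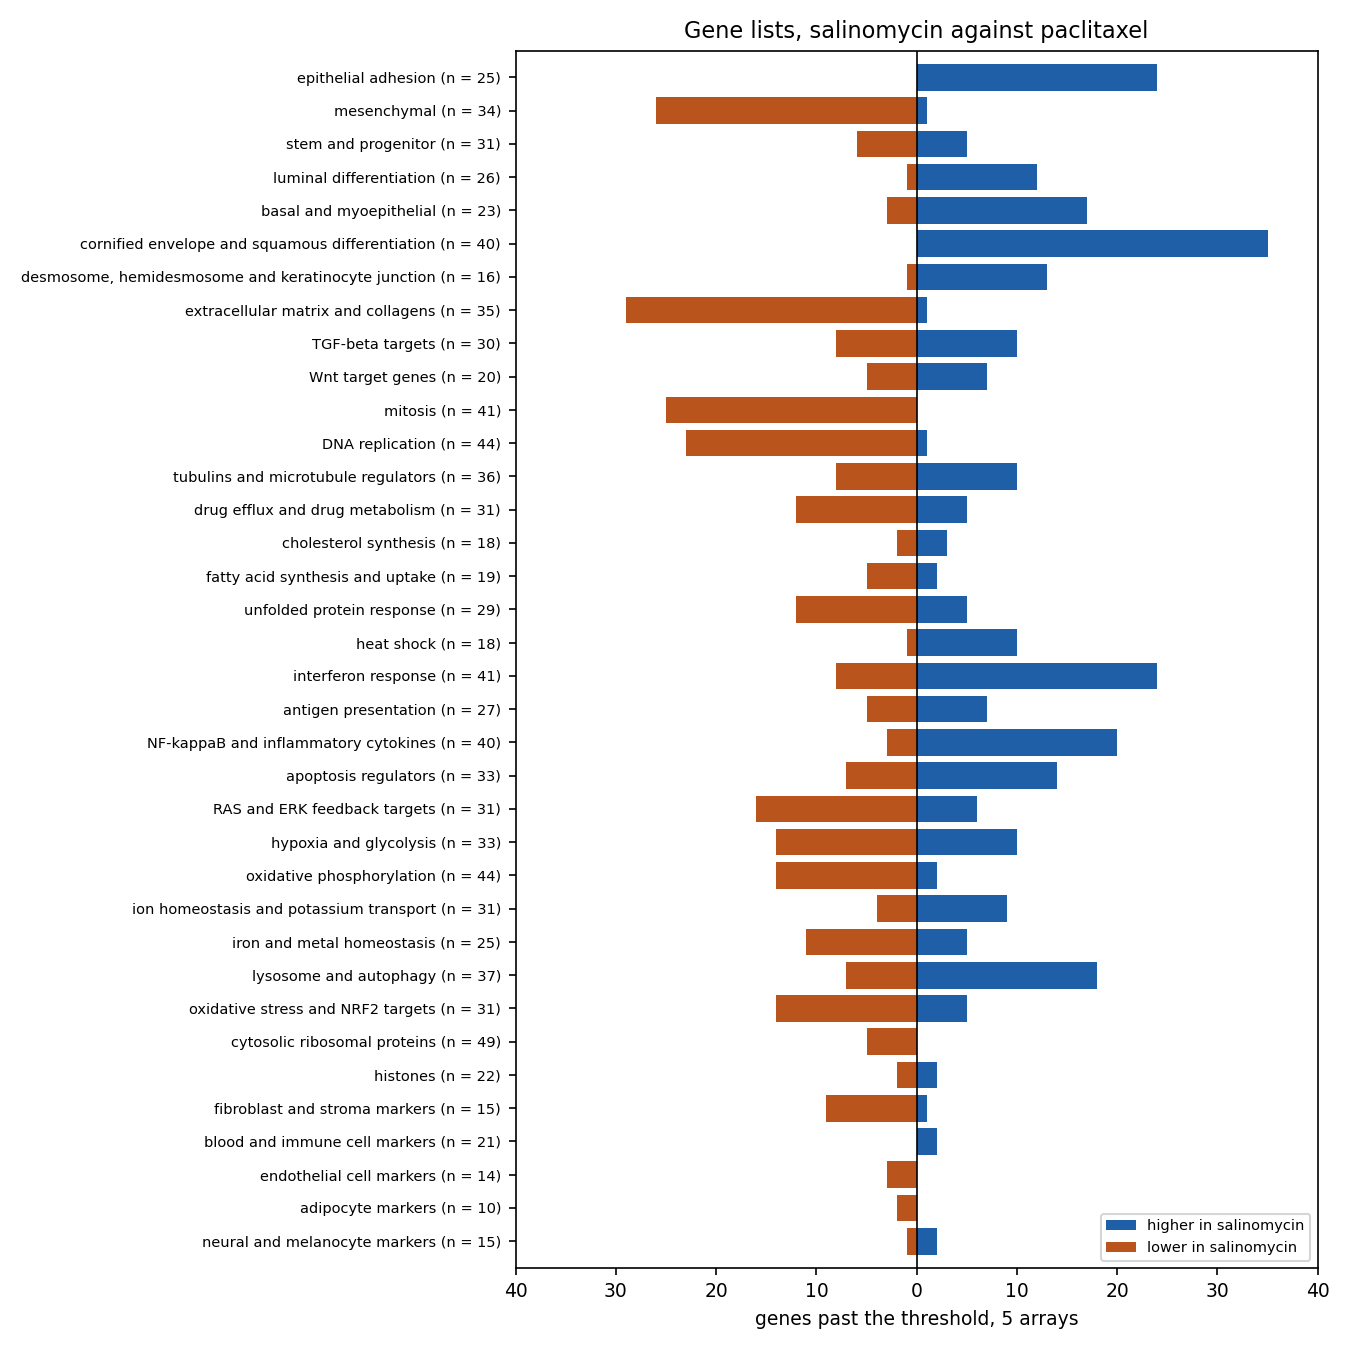
Number of measured genes of each of 36 of the 37 lists that were higher (right, blue) or lower (left, orange) in salinomycin at a limma adjusted p under 0.05, without the array labelled paclitaxel replicate 3 (n = 3 and 2 arrays; the number in brackets is the list's measured genes). Cornified envelope genes had 35 of 40 higher, and matrix genes had 29 of 35 lower.

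With all 6 arrays, 15 of the 37 lists passed camera, 0 with an estimated correlation and 0 by fry, and without the array labelled paclitaxel replicate 3 the numbers were 16, 0 and 26. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. High correlation between genes does not account for every list lost with an estimated correlation. On 5 arrays the estimate was 0.892 for mitosis but -0.0126 for the cornified envelope list, below the preset 0.01. The camera adjusted p of the cornified envelope list still rose from 1.89e-21 to 0.0511. Where 1 member of a list was higher or 1 was lower on 5 arrays, leaving out a further array changed that count by at most 1.

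Markers of other cell types outside the stroma were few and mostly near background. Of 21 blood and immune markers 2 were higher and 19 did not pass, CD53 at 1.45 ± 0.11 among those higher, with a camera adjusted p of 0.509; without paclitaxel replicate 1 or 2, 2 were lower. Of 14 endothelial markers 3 were lower and 11 did not pass, with PECAM1 at -1.35 ± 0.12 and an adjusted p of 0.738; the list's median was 0.023 and its mean -0.11. Of 10 adipocyte markers 2 were lower and 8 did not pass, with PPARG at -2.19 ± 0.14 and an adjusted p of 0.296. Adjusted over the list alone, the blood, endothelial and adipocyte markers gave 2 higher, 2 lower and 2 lower. The 3-prime to 5-prime log2 signal of GAPDH was -0.213 ± 0.026 in the paclitaxel group and -0.174 ± 0.012 in the salinomycin group (SD, n = 3 each), a difference of 0.039 with an exact permutation p of 0.1, two-sided, the smallest the design allows. It was 0.024 without paclitaxel replicate 1, with an exact p of 0.2, and 0.028 with quantile normalization, with an exact p of 0.6. For ACTB the difference was -0.0015 with an exact p of 1. The 3-prime to middle differences were 0.052 for GAPDH and -0.025 for ACTB, with exact p of 0.2 and 0.5.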

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

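With all 6 arrays as labelled, limma called 0 genes under every alternative set in advance except 2. Array weights gave 4352 genes, of which 1636 differed at least 2-fold, and leaving out 1 array in turn gave 0 to 4622 genes and 0 to 1782 genes at least 2-fold apart, the higher ends without paclitaxel replicate 3 and 0 without any other array. The fits that drop this array or weigh it down are the ones that call genes. They change the spread within the paclitaxel group and the difference between the groups together, and which of these accounts for the calls was not tested. The 15 lists past camera's threshold became 0 with an inter-gene correlation estimated per list and 0 by fry. Deviations from the group means correlated at -0.20, -0.16 and -0.34 between the treatments for replicate numbers 1, 2 and 3. The array labelled paclitaxel replicate 3 shifts the paclitaxel mean and so enters all these values. They cannot tell whether the replicate number pairs the cultures. With the replicate number as a block, 0 genes and 16 lists passed and the epithelial minus mesenchymal score differed by 4.44.

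The repeat on 5 arrays was chosen after seeing the data, as were all its alternatives. Its 4622 genes (1782 at least 2-fold) became 2905 (1145) without probe sets of the _x_at and _s_at kinds, which leaves fewer genes to test, and 7414 (2761) when every probe set was tested. The other alternatives stayed within 1.5 times, and leaving out a further array gave 3485 to 4351 genes. With paclitaxel replicate 1 or 2 out, the lone paclitaxel array is assumed to vary like the others. The 16 lists became 0 with an estimated correlation and 26 by fry. Lists with an estimate below the preset 0.01 were lost too, such as the cornified envelope list at -0.0126. The loss therefore does not show that correlation between genes explains the 16 lists. The difference in the epithelial minus mesenchymal score, 6.82, was 6.15 with the offset, 7.72 without genes below the median level, 6.09 with the mean of probe sets, 5.38 without the _x_at and _s_at kinds and 8.30 with list medians; it kept its sign throughout, and the cause of these shifts was not tested. Of 109 genes named by the rule in the text, 96 kept direction and call in every alternative on 5 arrays that measured them. The direction of CD44 turned with the mean of probe sets, to 0.12 with 6 arrays and 0.17 with 5. Without the _x_at and _s_at kinds, ITGB1 turned to 0.15 and 0.17 and CADM3 to 0.039 and 0.081, and KCNMA1 to 0.023 with 6 arrays; the cause was not tested, but another probe set stands for the gene there. Values near the bacterial controls' 4.22 to 4.32 cannot show how far a gene lies below that level.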

Other observations

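Metal, transport and metabolic genes not described so far also separated paclitaxel replicates 1 and 2 from the salinomycin arrays; log2 differences are salinomycin minus paclitaxel with SE, without the array labelled paclitaxel replicate 3 (n = 3 and 2), by limma with Benjamini-Hochberg adjustment. MT1F was at -3.81 ± 0.35, MT1X at -3.14 ± 0.40 and MT1E at -3.11 ± 0.34; these metallothioneins, small proteins that bind zinc and copper, belong to a list of iron and metal genes of which 5 of 25 were higher, 11 were lower and 9 did not pass, also when adjusted over the list alone, and which did not pass camera (adjusted p = 0.273). Among ion transport genes, SCNN1A, a subunit of the epithelial sodium channel, was at 4.74 ± 0.09 and KCNK1, a potassium channel, at 4.34 ± 0.10, while the calcium-activated potassium channel KCNMA1 was at -3.45 ± 0.22, a value that was -0.0070 without probe sets of the _x_at and _s_at kinds. Of 33 hypoxia and glycolysis genes 10 were higher, 14 were lower and 9 did not pass (10 and 15 adjusted over the list alone), with an adjusted p of 0.629, a median of -0.16 and a mean of 0.061. The glucose transporter SLC2A1 was at 2.92 ± 0.08 and LOX, a collagen cross-linking enzyme, at -3.61 ± 0.53. Of 37 lysosome and autophagy genes 18 were higher, 7 were lower and 12 did not pass (18 and 8 adjusted over the list alone), with the cathepsin CTSH at 3.21 ± 0.26 and an adjusted p of 0.0959.

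Signalling lists went both ways. Of 30 TGF-beta targets 10 were higher, 8 were lower and 12 did not pass (11 and 8 adjusted over the list alone), with an adjusted p of 0.514; BAMBI, a decoy receptor, was at 5.05 ± 0.12 and LTBP1, which stores latent TGF-beta in the matrix, at -5.03 ± 0.20. Of 20 Wnt targets 7 were higher, 5 were lower and 8 did not pass, also when adjusted over the list alone, with an adjusted p of 0.273; the Wnt antagonists SFRP1 and DKK1 were at 3.23 ± 0.16 and 2.31 ± 0.33 and MMP7 at -3.06 ± 0.28. Antigen presentation (7 higher, 5 lower and 15 not past the threshold of 27, HLA-F at 1.58 ± 0.09, adjusted p = 0.446), cholesterol synthesis (3, 2 and 13 of 18, LSS at -1.46 ± 0.15, adjusted p = 0.738) and fatty acid synthesis (2, 5 and 12 of 19, FADS1 at -2.38 ± 0.14, adjusted p = 0.273) had the same numbers when adjusted over the list alone. HLA-F was at 0.37 without probe sets of the _x_at and _s_at kinds and did not pass there. Fatty acid synthesis passed camera at an adjusted p of 0.0481 without paclitaxel replicate 1, and had 0.856 without paclitaxel replicate 2. Without paclitaxel replicate 1 the lower members numbered 9 for cholesterol and 10 for fatty acid synthesis, and without paclitaxel replicate 2 the higher members numbered 5 and 4. The lower members numbered 3 for antigen presentation and for fatty acid synthesis without salinomycin replicate 1 or 2, 3 for Wnt targets without paclitaxel replicate 2 or salinomycin replicate 1, and 8 and 9 for hypoxia genes without salinomycin replicates 1 and 2. Of 49 ribosomal protein genes 0 were higher, 5 were lower and 44 did not pass (0 and 2 adjusted over the list alone), with an adjusted p of 0.0847, and of 22 histone genes 2 were higher, 2 were lower and 18 did not pass (1 and 2), with an adjusted p of 0.618. The ribosomal list passed at an adjusted p of 0.0132 without paclitaxel replicate 2, where 7 were lower, within a range up to 0.279 over 12 alternatives, and had 2 lower without salinomycin replicate 1 and 3 without any 1 of the other arrays. Histone genes had 8 higher without paclitaxel replicate 2, 1 higher and 4 lower without paclitaxel replicate 1, and 1 higher and 1 lower without salinomycin replicate 1 or 2. Neural and melanocyte markers had 2 higher, 1 lower and 12 not past the threshold of 15, also when adjusted over the list alone, with MITF at 2.04 ± 0.07, NEFL at -2.91 ± 0.17 and an adjusted p of 0.738; camera's direction was up while the median was -0.015 and the mean -0.034.

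The tests below were chosen only after the result was seen, except the 3 counts over other splits of the arrays and the test of a shared paclitaxel change.

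The array labelled paclitaxel replicate 3 lay with the salinomycin arrays. A swap that left an array with the pattern of paclitaxel replicates 1 and 2 under a salinomycin label is argued against. The highest correlation of a salinomycin array with either was 0.925, below the lowest of 0.996 between salinomycin arrays. Salinomycin replicate 3 differed at least 2-fold from salinomycin replicates 1 and 2 in 44 genes each, and those from each other in 4. Whether the array labelled paclitaxel replicate 3 was swapped with a paclitaxel culture that lacked the mesenchymal pattern cannot be told from these correlations. A single wrong label, or RNA from a culture that did not carry the paclitaxel pattern, is a possible explanation, since the array's largest median absolute difference from a salinomycin array was 0.0977, no more than the 0.111 found between salinomycin arrays. Whether it was a paclitaxel culture that kept a small part of the change cannot be told apart from this, because the correlation of its deviations with the paclitaxel change had a median of -0.0220 and ran from -0.334 to 0.00212 over 6 choices of salinomycin arrays. A paclitaxel culture in which no mesenchymal population grew out also remains open and untested, since the design has no untreated array to compare it with.

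Salinomycin replicate 3 lay above the other salinomycin arrays in part of the genes that mark paclitaxel replicates 1 and 2. In it 30 genes were at least 2-fold above salinomycin replicates 1 and 2 and the array labelled paclitaxel replicate 3, and 90% of them, against 7.88% of all genes, were at least 2-fold higher in paclitaxel replicates 1 and 2. Array noise is argued against, since 10 of the 21 genes at least 32-fold higher in paclitaxel replicates 1 and 2 than on average in salinomycin replicates 1 and 2 and the array labelled paclitaxel replicate 3 were raised 2-fold in this array and 0 in each of the 3 others. Those 3 arrays are part of the mean they were compared with, which narrows their values here and in the shares below. Compared over all genes as the 30 were, 0 genes were raised in the array labelled paclitaxel replicate 3, 0 in salinomycin replicate 1 and 1 in salinomycin replicate 2. An admixture of cells with the average profile of paclitaxel replicates 1 and 2 is argued against as well, because the share it would need ran from 0.0333% (10th percentile) to 13.4% (90th percentile) of the RNA over these 21 genes, against -0.361% to 0.423% in the 3 other arrays, with 26.8% for PTX3 (chosen after its values were seen) and 0.181% for COL3A1. A small mesenchymal population of another composition may remain in that culture, which these data do not test.

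With 10 splits of the 6 arrays into 3 and 3, a share under 0.05 cannot be reached. As labelled, 0 genes passed and the highest of the other splits was 0, so all 10 splits gave as many, and the same held for genes at least 2-fold apart, again in 10 of 10. For lists the labelled split gave 15 and the highest other 16, with 4 of 10 splits giving as many as labelled, and these 4 were the splits that kept paclitaxel replicates 1 and 2 together, which points to the structure of the arrays described above. At an unadjusted p under 0.05 the labelled split gave 825 genes, and the highest other, with paclitaxel replicates 1 and 2 and salinomycin replicate 3 together, gave 2088. The 4 splits that kept paclitaxel replicates 1 and 2 together gave 825 to 2088 genes, and the other splits gave 49 to 70. The labelled split gave the fewest of those 4.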
